A study of Mus musculus with 6 samples.

How the data were processed

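The data were bulk RNA-seq libraries from cultured mouse neural stem cells, 3 of a control group and 3 labelled as a Sirt6 knockout. Per the labels' protocols, cells of postnatal day 7 mice were grown in DMEM/F12 with EGF and bFGF (20 ng/ml of each), B27 at 2% and BSA at 0.2%, RNA was extracted with TRIzol on day 7 of culture, and 2 µg per sample went into libraries made with the NEBNext Ultra RNA kit. HISAT2 2.1.0, Bowtie2 2.2.3 and the genome build mm10 are named in the submitters' processing notes, without their roles. The counting tool, its strand setting and the annotation release are not given in the sources used here. In GENCODE M21 (GRCm38), 99.8% of the gene IDs were found, and 94.6% of those had the same start and end.

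The deposited table holds raw whole-number counts per gene for each of the 6 libraries, per the file headers and the values. Beside them it holds the authors' own comparison: a mean of scaled counts, a fold change (ratio), a log2 ratio, a p-value and an adjusted p-value, each deposited as 1 column. The authors' ratio and log2 columns are control over knockout, checked against the counts. The authors' mean column equals the mean of counts scaled by DESeq2's size factors within 0.1% for 100% of genes, and the log2 column differs from a DESeq2 fit by a median of 1.0e-05. The table lists 27372 genes with a name, of which 17284 carry the authors' adjusted p-value. A line with no gene name was left out.

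Samples were grouped by the labels. Totals were 17198852, 18297275 and 17855941 counts in control replicates 1 to 3 and 18096866, 17222744 and 17573394 in the libraries labelled knockout, with TMM factors from 0.973 to 1.03. On the TMM-scaled library sizes 1 CPM stands for 16.7 to 18.6 counts, so the values of the rarest genes named carry counting error as well as replicate spread. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes with at least 60 counts in total was 19.4 or more for all pairs, so each library was counted as its own sample.

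Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, filterByExpr on group (minimum count 10, minimum total 15), robust dispersions, glmQLFit and glmQLFTest with an intercept and the group, all 6 libraries, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 on the same fit, adjusted over the lists. Annotation terms with 15 to 300 tested genes were tested likewise, adjusted within each of the 3 annotations. Where a symbol stands for more than 1 gene ID, the ID with the most counts was used in the lists.

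The lists, the design and most of the alternatives were written before the data were examined. The lists covered cell types of neurosphere cultures, other cell types, proliferation, stress, programmes linked to SIRT6, signalling pathways, metabolism, regional identity and RNA quality. The rule for naming genes took Sirt6 first, then genes past the edgeR threshold with groups apart and a mean of at least 2 CPM (there were 0, so the 12 largest and 12 smallest fold changes named none), then from each list up to 4 members past the threshold or else at most the 1 with the highest mean CPM. By that rule came Sirt6, Ptprz1, Map1b, Apoe, Olig1, Mki67, Rrm1, Cdkn1a, Igfbp3, Parp1, Eno1, Ddit4, Ncl, Sod2, Peg3, Ccnd1, Hmgcs1 and Sirt2. After the values were seen, the naming was narrowed to the called lists, the neural stem cell list and the senescence list. All other genes named were chosen after their values were seen.

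Alternatives chosen beforehand were DESeq2 1.42.0, limma-voom, RLE size factors, scaling by total counts, no filter, a stricter filter (1 CPM in 3 libraries), the replicate number as a block, a test against a 1.5-fold change, each library left out in turn, camera with an estimated correlation and fry. Added after seeing the data were DESeq2, limma-voom and camera with estimated correlation under the block, the block for annotation terms, the summed CPM of 4 Y-linked genes as a covariate (for the mitotic score in linear fits, with and without the block), and the 3 libraries labelled knockout against control replicate 3 alone, where the lone control is assumed to vary like the other group.

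Titles give both groups the replicate numbers 1 to 3. After subtraction of group means, the log2 CPM of same-numbered libraries correlated at 0.43, 0.35 and 0.51 across genes, and the numbered pairing had the highest mean correlation (0.43) of the 6 possible pairings, the next being 0.10. The numbers were treated as a possible pairing, used as a block in alternative fits, while the main fit used the group alone. With only 6 possible pairings a first rank can arise by chance, and the correlations run across genes that are not independent. The numbers come from the titles, and the block for edgeR and camera was chosen beforehand. That the numbers mark pairs rests on these correlations, since the labels name no shared litter, batch or day.

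The procedures were tested on simulated data with the real means, dispersions and library sizes and 200 changed genes. Camera called a list of 25 genes moved 1.5-fold and 0 of 100 random lists, with a preset and with an estimated correlation. The simulated genes varied independently, unlike the members of a real list. The test of neighbouring genes gave fewer than 5% of runs in 3.5% of 200 draws of chance p-values.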

Results

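RNA sequencing was carried out on mouse neural stem cells taken at postnatal day 7 and grown as neurospheres, floating clusters of dividing progenitors, in medium with the mitogens EGF and bFGF. RNA was taken on day 7 of culture. The 6 libraries fell into 2 groups of 3, a control group of wild-type genotype and a group labelled as a conditional knockout of Sirt6, a nuclear NAD-dependent deacylase that acts on histones. The question was how loss of Sirt6 changes gene expression in these cells. Library totals ran from 17198852 to 18297275 counts over 27372 genes. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical, although the 3 controls differ in sex-linked transcripts and so are not repeats of the same cells.

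Sirt6 itself was higher, not lower, in the libraries labelled knockout. Its counts were 380, 293 and 260 in control replicates 1, 2 and 3, and 474, 492 and 442 in the libraries labelled knockout. As CPM, counts scaled to a common library size, this was 17.5 ± 3.80 (SD, n = 3) in the controls and 26.8 ± 2.29 (SD, n = 3) in the libraries labelled knockout, a log2 fold change of 0.61 with a standard error of 0.19. All 3 libraries labelled knockout lay above all 3 controls, but the difference did not pass edgeR's quasi-likelihood test over all genes (unadjusted p = 0.0146, adjusted p = 0.998). With the replicate number as a block, edgeR's adjusted p was 0.216 and that of DESeq2 was 0.10. Sirt6 (ENSMUSG00000034748) lies on the minus strand of chromosome 10 from 81621785 to 81627797 in mm10, and no other gene of the table overlaps it. In the authors' deposited table its log2 ratio of control over knockout is -0.61, with an adjusted p of 0.848. The counts cover the whole gene, so a transcript that lost only some of its exons would still be counted. Because the targeted gene goes against the labels, every direction below is stated for the libraries labelled knockout, and none is a direction of Sirt6 loss.

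**Figure D1:**
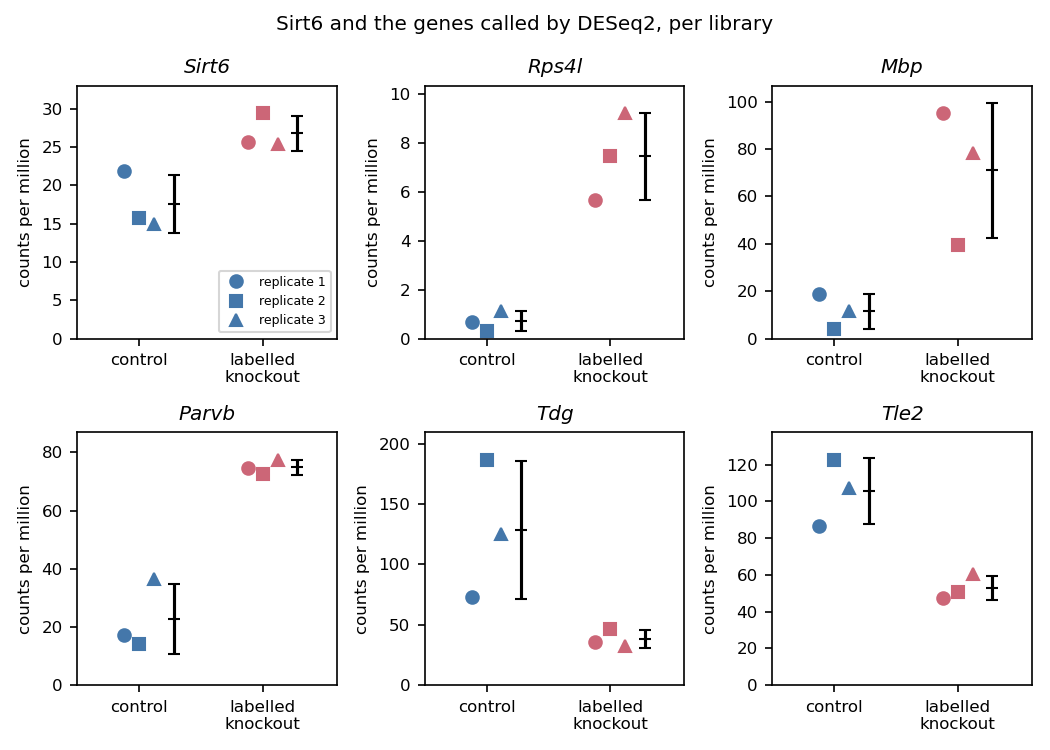
CPM (linear axis from 0) of Sirt6 and of the 5 genes called by DESeq2, for each control library (blue) and each library labelled knockout (red); symbols mark the replicate number, and the bar beside each group is its mean with 1 SD. Sirt6 averages 17.5 CPM in the controls and 26.8 CPM in the libraries labelled knockout, and in each of the 6 genes the groups do not overlap.

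The clearest single-gene differences were in Mbp, which encodes the major myelin basic protein, Parvb, which encodes the focal adhesion protein beta-parvin, and Rps4l, a copy of a ribosomal protein gene, all higher in the libraries labelled knockout. Tdg, a DNA glycosylase that removes mismatched thymine and oxidised methylcytosine, and Tle2, a transcriptional corepressor, were lower there. Mbp stood at 11.5 ± 7.25 CPM in the controls and 71.0 ± 28.5 CPM in the libraries labelled knockout (SD, n = 3 each), a log2 fold change of 2.63 ± 0.56 (SE). Parvb went from 22.6 ± 12.1 to 74.9 ± 2.52 CPM and Rps4l from 0.719 ± 0.412 to 7.46 ± 1.78 CPM. Tdg stood at 128 ± 57.2 CPM in the controls against 38.2 ± 7.48 CPM, and Tle2 at 105.5 ± 18.2 against 52.8 ± 6.76 CPM. These 5 were the genes called by DESeq2 at an adjusted p under 0.05, with adjusted p of 7.1e-09 for Rps4l, 9.4e-04 for Mbp, 0.00276 for Tdg, 0.00584 for Parvb and 0.0208 for Tle2. They were chosen after their values were seen. The reads of Rps4l are uncertain, since its sequence resembles that of other ribosomal protein S4 genes and it lies within Tmtc1 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

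Over all genes, edgeR called 0 of the 15087 genes tested at an adjusted p under 0.05 and 524 at an unadjusted p under 0.05, of which 298 were higher and 226 lower in the libraries labelled knockout. Limma-voom called 0, DESeq2 called 5, and edgeR without a filter on low counts called 1, Rps4l. All 3 libraries labelled knockout lay above the controls in 736 genes and below them in 562, together 8.60% of the genes tested, where chance gives 10% if the libraries are not paired. Without control replicate 3 or the library labelled knockout 2, the count at an unadjusted p under 0.05 was 790 and 1025. Leaving out control replicate 1 gave 1 call by edgeR, the unnamed gene Gm9855, and leaving out control replicate 3 gave 2, Parvb and the Y-linked Ddx3y. In counts simulated for this comparison over 15087 genes, edgeR recovered 60 of 66 genes changed 4-fold, 19 of 67 changed 2-fold and 2 of 67 changed 1.5-fold, with 6 unchanged genes called. DESeq2 recovered 65, 38 and 4 of these, with 48 unchanged genes among its 155 calls. These recoveries hold for the simulated number of changed genes, since the adjustment eases as more genes have small p-values. They do not show that a 4-fold change would be called in the real counts. There edgeR gave an adjusted p of 0.998 to Rps4l, 10.3-fold higher in the libraries labelled knockout, and to Mbp, 6.19-fold higher.

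The authors' deposited table lists an adjusted p under 0.05 for 6 genes: Rps4l, Mbp, Parvb, Tdg, Tle2 and Pdzrn3, a ubiquitin ligase gene. It marks 5 of them as significant and leaves out Tle2, whose log2 ratio of control over knockout is just under 1. The edgeR fit gave all 6 the same direction as the authors' deposited table, and called 0 of them.

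Same-numbered libraries of the 2 groups correlated after subtraction of group means, a pairing that the labels do not state. A model with the replicate number as a block compares within numbers. With the block, edgeR called 0 genes, with Mbp at the smallest adjusted p (0.0715), and 1880 genes had an unadjusted p under 0.05. Limma-voom with the block called 0 genes and had 1909 at an unadjusted p under 0.05. DESeq2 with the block, an alternative chosen after seeing the data, called 465 genes, 153 higher and 312 lower in the libraries labelled knockout. These included all 5 genes called by DESeq2 without the block. In the simulated counts, which carried no pairing, DESeq2 with the block called 52 unchanged genes among 156.

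**Figure D2:**
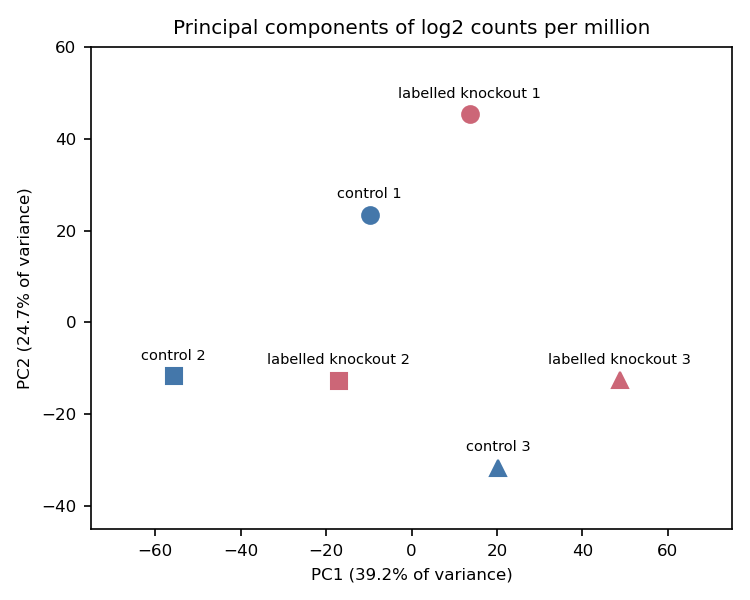
Position of the 6 libraries on the first 2 principal components of log2 CPM over the genes tested; PC1 (horizontal) holds 39.2% of the variance and PC2 (vertical) 24.7%, colour marks the group and symbol the replicate number. Control replicate 2 lies at -55.7 and the library labelled knockout 3 at 48.7 on PC1, and the groups do not separate. Within each replicate number the library labelled knockout lies higher on PC1 than the control (13.6 against -9.81, -17.1 against -55.7 and 48.7 against 20.3). On PC2 the direction differs between the numbers.

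Among the 119 of those 465 genes that had an official symbol, a mean of at least 2 CPM in the higher group and groups that did not overlap, 67 were higher and 52 lower. All genes named from this set were chosen after their values were seen. Higher in the libraries labelled knockout were Selenop, the plasma selenium carrier, with a blocked DESeq2 log2 fold change of 1.63 ± 0.19 (SE), and Gfap, the astrocyte intermediate filament, with 2.17 ± 0.59. Sox10, a transcription factor of the oligodendrocyte lineage, stood at 1.85 ± 0.39, and Ntsr2, a neurotensin receptor of astrocytes, at 1.63 ± 0.32. Lower were Hmcn1, which encodes a large extracellular matrix protein, at -2.44 ± 0.34, Pou3f1, a POU-domain transcription factor, at -1.88 ± 0.32, and Gabra2, a GABA receptor subunit, at -1.26 ± 0.22. Synpr, a synaptic vesicle protein gene, stood at -1.82 ± 0.39 and Ckmt1, a mitochondrial creatine kinase gene, at -1.56 ± 0.32. Hmcn1 varied widely within the controls (34.9 ± 40.0 CPM, SD, n = 3).

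The libraries also differed in their content of sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had 32116, 9 and 36131 counts in control replicates 1, 2 and 3, and 62927, 51663 and 39689 in the libraries labelled knockout. The summed level of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty was 67.5, 234 and 0 CPM in the controls and 0.755, 0.12 and 0 CPM in the libraries labelled knockout. Y-linked reads were thus present in number in control replicates 1 and 2 only. Beside each called list below stands its value with the Y-linked level as a covariate, an alternative chosen after seeing the data. The level is near 0 in all 3 libraries labelled knockout, so the slope of this covariate rests on the controls. The fit thus leans on control replicate 3 and is not independent of the comparison with control replicate 3 alone. Neither separates the Y-linked level from other differences among the controls.

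Of the 41 gene lists fixed before the data were examined, 34 had at least 5 tested members, and camera with a preset correlation called 15 of them, 8 higher and 7 lower in the libraries labelled knockout. With an estimated correlation it called 0, the smallest adjusted p being 0.264. The estimated correlation between members was 0.98 in the mitotic, 0.96 in the DNA replication and 0.96 in the cholesterol synthesis list. That is far above the preset 0.01, so the calls of these lists at the preset overstate the evidence. In the oligodendrocyte lineage list the estimate was -0.012, so a correlation above the preset is not what lost its call. The other called lists lay between these values. With the replicate block camera called 13, and leaving out the library labelled knockout 2 left 7.

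Oligodendrocyte lineage genes rose as a list in the libraries labelled knockout, with a mean log2 fold change of 0.65 over 18 tested members (camera adjusted p = 3.2e-05; adjusted p = 0.264 with an estimated correlation). The list split by member: 11 were higher and 7 lower. Among the higher were the transcription factor gene Sox10 at 1.75 ± 0.51 (log2, SE), Mbp, Cnp at 0.90 ± 0.21, Enpp6 at 1.62 ± 0.59, Bcas1 at 1.35 ± 0.53 and Myrf at 1.06 ± 0.39. Among the lower were the transcription factor genes Olig2 at -0.53 ± 0.19 and Olig1 at -0.47 ± 0.21, and Cspg4, the NG2 proteoglycan, at -1.02 ± 0.33 (adjusted p = 0.440 by DESeq2 with the block). No division of the list by stage was fixed or tested. Of these only Olig1 was named by the rule fixed beforehand. By edgeR, 0 members passed over all genes tested and 2, Mbp and Cnp, adjusted over the list alone. DESeq2 with the block called 9 members higher and 2, Olig1 and Olig2, lower. Each same-numbered pair differed in the same direction, by 0.77, 0.72 and 0.61 in the mean log2 level of the list. With the Y-linked covariate the mean was 0.50 (camera adjusted p = 4.0e-04), and against control replicate 3 alone it was 0.89. Cnp overlaps Dnajc7 on the opposite strand (124 CPM on average, against 334 CPM), and reads of such a pair cannot be assigned without the strand.

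Astrocyte genes rose as a list, with 20 of 21 tested members higher and a mean log2 fold change of 0.63 (camera adjusted p = 3.8e-08; adjusted p = 0.592 with an estimated correlation). By edgeR 0 members passed, either over all genes tested or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Gfap was the largest of these, at 175 ± 110 CPM in the controls and 708 ± 417.5 CPM in the libraries labelled knockout (SD, n = 3 each). Apoe, a lipid carrier and the most abundant member, stood at a log2 fold change of 0.88 ± 0.70 (SE). DESeq2 with the block called 7 members, all higher. The mean was 1.16 without control replicate 3, 0.32 without control replicate 2 and 0.30 without the library labelled knockout 3. With the Y-linked covariate the mean was 0.11 (camera adjusted p = 0.547), and against control replicate 3 alone it was -0.0096 (camera adjusted p = 0.647).

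Neuroblast and immature neuron genes rose with a mean of 0.44 over 20 members, 16 of them higher (camera adjusted p = 9.2e-04; adjusted p = 0.592 with an estimated correlation), and 0 passed adjusted over the list alone. Map1b, a microtubule-associated protein of growing axons, stood at 0.72 ± 0.21 and Gad1, a GABA-synthesising enzyme, at 0.78 ± 0.23. The mean with the Y-linked covariate was 0.39 (camera adjusted p = 0.00533). Without the library labelled knockout 1 it was 0.08 (camera adjusted p = 0.414). Genes of neural stem cells and radial glia, the cell type under study, were not called: 12 members were higher and 8 lower, with a mean of -0.01 and a median of 0.05 (camera adjusted p = 0.935), and the most abundant, Ptprz1, stood at -0.12 ± 0.19. Nor were mature neuron and synapse genes (adjusted p = 0.412).

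Mitotic genes fell as a list, with all 26 members lower and a mean log2 fold change of -0.83 in the libraries labelled knockout (camera adjusted p = 2.0e-14; adjusted p = 0.592 with an estimated correlation). Mki67, the proliferation antigen Ki-67, stood at 525 ± 292 CPM in the controls and 280 ± 192 CPM in the libraries labelled knockout (SD, n = 3 each), within the spread of the unpaired replicates. It was lower in each same-numbered pair, with a log2 fold change of -0.98 ± 0.14 (SE) by DESeq2 with the block (adjusted p = 4.9e-09). By edgeR with the block the adjusted p of Mki67 was 0.090. Foxm1, a transcription factor of the G2/M genes, stood at -1.04 ± 0.45 and Cdc20, an activator of the anaphase-promoting complex, at -1.05 ± 0.54, the latter overlapping Elovl1 on the opposite strand (36.5 CPM on average, against 95.9 CPM). DNA replication genes fell too, all 27 members being lower, with a mean of -0.67 (camera adjusted p = 1.5e-12; adjusted p = 0.592 with an estimated correlation), among them Uhrf1 at -0.99 ± 0.51 and the ribonucleotide reductase gene Rrm1 at -0.50 ± 0.39. Over all genes tested or adjusted over the list alone, edgeR called 0 members of either list. Over all genes tested, edgeR with the block called 0 as well. DESeq2 with the block called 26 of the mitotic and 19 of the replication genes, all lower.

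The mitotic score, the mean centred log2 level of the list, was -0.21 to 1.22 in the controls and -1.23 to 0.62 in the libraries labelled knockout. Its pair differences were -1.23, -0.60 and -1.01. The mean fold change was -0.37 without control replicate 2, -0.51 without the library labelled knockout 3 and -1.59 without the library labelled knockout 2. For the replication genes the same settings gave -0.22, -0.39 and -1.07. Under the Y-linked covariate the mitotic mean was -0.13 (camera adjusted p = 0.0510) and the replication mean -0.04 (adjusted p = 0.324).

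**Figure D3:**
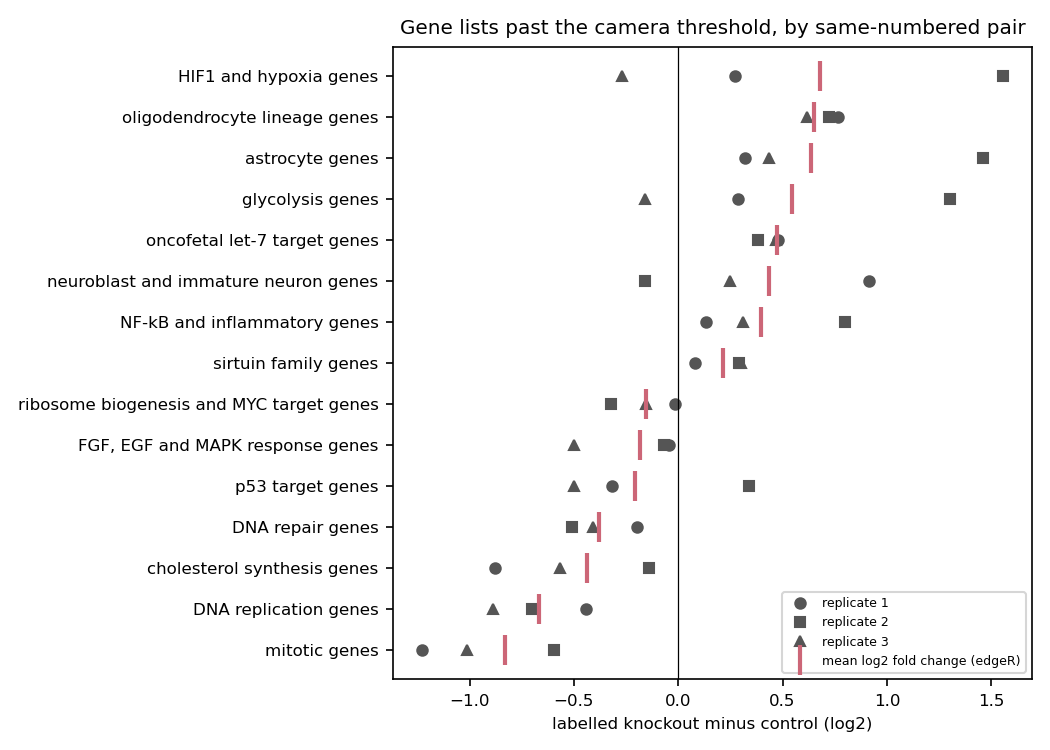
Difference of each gene list past the camera threshold between the library labelled knockout and the control of the same replicate number (dark symbols), on a log2 scale, with the mean log2 fold change of the list's members in the edgeR fit (red bar). The mitotic list lies below 0 in all 3 pairs and the oligodendrocyte lineage list above 0 in all 3, while the hypoxia list ranges from -0.27 to 1.56.

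DNA repair genes fell as a list, with 21 of 25 members lower and a mean of -0.38 (camera adjusted p = 3.5e-05; adjusted p = 0.592 with an estimated correlation). Parp1, which senses strand breaks, stood at -0.14 ± 0.17, and Fanca, of the Fanconi anaemia pathway, at -0.94 ± 0.44, though Fanca overlaps Zfp276 on the opposite strand (29.4 CPM on average, against 21.4 CPM). Without control replicate 2 the mean was -0.12 (camera adjusted p = 0.131), and with the Y-linked covariate it was -0.03 (adjusted p = 0.800). Cholesterol synthesis genes fell as a list, with 18 of 19 members lower and a mean of -0.44 (camera adjusted p = 5.7e-07; adjusted p = 0.592 with an estimated correlation). Mvk, mevalonate kinase, stood at -0.68 ± 0.27 and Hmgcs1, an early enzyme of the pathway, at -0.22 ± 0.49. The Y-linked covariate gave a mean of -0.04 (camera adjusted p = 0.289). The mean was -0.18 without control replicate 2, and -0.24, -0.98 and -0.22 without the libraries labelled knockout 1, 2 and 3. In each of these lists edgeR called 0 members adjusted over the list alone.

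Genes that respond to FGF and EGF signalling fell slightly, with a mean of -0.18 over 20 members, 13 of them lower (camera adjusted p = 0.00390; adjusted p = 0.592 with an estimated correlation). Spry1 and Spry4, feedback inhibitors of the pathway, stood at -0.91 ± 0.25 and -0.98 ± 0.28, and Ccnd1, which encodes cyclin D1, at 1136 ± 106 CPM in the controls against 616 ± 286 CPM (SD, n = 3 each). The mean with that covariate was -0.24 (camera adjusted p = 0.00189). The call was lost without control replicate 3 (-0.13, adjusted p = 0.0914) and without the library labelled knockout 2 (-0.20, adjusted p = 0.0627), and the mean was -0.29 without the library labelled knockout 1 and -0.09 without the library labelled knockout 3. DESeq2 with the block called 5 members, all lower, and edgeR called 0 adjusted over the list alone.

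HIF1 and hypoxia genes rose as a list, with 15 of 16 members higher and a mean of 0.68 (camera adjusted p = 3.5e-05; adjusted p = 0.592 with an estimated correlation), as did glycolysis genes, with 21 of 24 members higher and a mean of 0.54 (camera adjusted p = 3.5e-05; adjusted p = 0.592 with an estimated correlation). Kdm3a, a histone demethylase induced by hypoxia, stood at 0.52 ± 0.18, and the neuronal glucose transporter gene Slc2a3 at 0.78 ± 0.44. Ddit4 and Eno1, the most abundant members, stood at 0.23 ± 0.34 and 0.18 ± 0.30. Replicate 2 carried most of both differences: the pairs differed by 0.27, 1.56 and -0.27 for hypoxia and by 0.29, 1.30 and -0.16 for glycolysis. Without the library labelled knockout 2 the means were 0.29 (camera adjusted p = 0.262) and 0.34 (adjusted p = 0.134), and without control replicate 1 they were 1.06 and 0.84. Adding the Y-linked covariate gave 0.55 (adjusted p = 0.0124) and 0.36 (adjusted p = 0.231). In neither list did edgeR call a member adjusted over the list alone.

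Of the remaining called lists, ribosome biogenesis and MYC target genes fell as a list, 22 of 24 members being lower, with a mean of -0.15 (camera adjusted p = 0.00102; adjusted p = 0.602 with an estimated correlation), with Ncl, nucleolin, at -0.20 ± 0.23. NF-kB and inflammatory genes rose as a list, 9 of 12 members being higher, with a mean of 0.40 (camera adjusted p = 0.0265; adjusted p = 0.592 with an estimated correlation), with Sod2, a mitochondrial superoxide dismutase gene and the most abundant member, at -0.11 ± 0.14. Beside the Y-linked covariate these means were -1.1e-04 and 0.13, with adjusted p of 0.800 and 0.898. Sirtuin family genes rose by a mean of 0.21 and a median of 0.09 over 7 members, 4 higher and 3 lower, with Sirt2 at 0.70 and the targeted gene Sirt6 itself at 0.61 carrying most of the mean (camera adjusted p = 0.0274; adjusted p = 0.592 with an estimated correlation). Sirt2, an abundant cytoplasmic deacetylase of oligodendrocytes, stood at 301 ± 64.8 CPM in the controls and 489 ± 44.1 CPM in the libraries labelled knockout (SD, n = 3 each), and was the 1 member that passed adjusted over the list alone by edgeR (adjusted p = 0.0488); it overlaps Nfkbib on the opposite strand (27.8 CPM on average, against 395 CPM). The sirtuin call was lost without control replicate 2 (0.13, adjusted p = 0.131), the library labelled knockout 2 (0.28, adjusted p = 0.0528) or the library labelled knockout 3 (0.09, adjusted p = 0.283). Its mean with the Y-linked covariate was 0.09 (adjusted p = 0.308). Without control replicate 2 or the library labelled knockout 2, the ribosome biogenesis list stood at -0.05 and -0.16 (adjusted p = 0.270 and 0.0528) and the NF-kB list at 0.23 and 0.43 (adjusted p = 0.363 and 0.0618). The NF-kB call was also lost with the stricter filter on low counts (0.36, adjusted p = 0.0515).

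The p53 target list fell by a mean of -0.21, with 17 of 20 members lower (camera adjusted p = 0.0329; adjusted p = 0.819 with an estimated correlation), and was not called with the replicate block (adjusted p = 0.0545). Cdkn1a, the p53-induced CDK inhibitor p21, stood at -0.21 ± 0.50. The list's mean was -0.38 without control replicate 2. It was 0.10 without control replicate 3, -0.11 without the library labelled knockout 1 and -0.25 without the library labelled knockout 2, with adjusted p of 0.540, 0.544 and 0.0559. The Y-linked covariate gave -0.50 (camera adjusted p = 9.9e-13). The list named oncofetal let-7 target genes, some of them known targets of SIRT6 in embryonic cells, rose by a mean of 0.47 over 15 members, 10 of them higher (camera adjusted p = 0.0340, and 0.592 with an estimated correlation). It was not called with the block (adjusted p = 0.0755). The name of the list does not establish its members Cdkn1c and Peg3 as let-7 targets. Cdkn1c, an imprinted CDK inhibitor, stood at 2.43 ± 1.06 CPM in the controls and 6.65 ± 1.85 CPM in the libraries labelled knockout (SD, n = 3 each), and Peg3, the most abundant member, at a log2 fold change of -0.38 ± 0.27 (SE). The mean was 0.93 without control replicate 1. Without the library labelled knockout 1 it was -0.018 (adjusted p = 0.970), without control replicate 3 it was 0.33 (0.383), without control replicate 2 it was 0.40 (0.103), without the library labelled knockout 2 it was 0.58 (0.0661), and with the Y-linked covariate it was 0.39 (0.0957), all camera adjusted p. In all 4 of the ribosome biogenesis, NF-kB, p53 and let-7 lists, edgeR called 0 members adjusted over the list alone.

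Against control replicate 3 alone, the 1 control without Y-linked reads, the means of several lists lay near 0. They were -0.02 for the mitotic, -0.08 for the DNA replication, 0.021 for the cholesterol synthesis, -0.06 for the DNA repair and 0.0036 for the ribosome biogenesis list. The other means were 0.36 (NF-kB), 0.10 (sirtuin), -0.61 (p53), 1.06 (let-7), 1.10 (hypoxia), 0.83 (glycolysis), 0.76 (neuroblast) and -0.23 (FGF and EGF). This fit sets 1 control against all 3 libraries labelled knockout and so ignores the replicate numbers. Within pair 3 the mitotic list differed by -1.01, DNA replication by -0.89, cholesterol synthesis by -0.57, DNA repair by -0.41 and astrocyte genes by 0.435. Hypoxia and glycolysis differed there by -0.27 and -0.16, against the sign of their means.

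The other 19 tested lists were not called, with a smallest adjusted p of 0.0756 for oxidative phosphorylation. They covered the Notch (adjusted p = 0.0907), Wnt (0.525), Hedgehog (0.880), and BMP and TGF-beta (0.935) pathways, insulin and IGF signalling (0.396), interferon-stimulated genes (0.935), MHC class I (0.935), NRF2 and antioxidant (0.206), ATF4 and unfolded protein response (0.542), fatty acid and lipid (0.765), extracellular matrix (0.357) and forebrain identity genes (0.672), all by camera. Mean, median and the direction of the test differed in sign for the forebrain, fatty acid, MHC, BMP, mitochondrial and neural stem cell lists. Not called either were mitochondrially encoded genes (0.765), ribosomal protein genes (0.672), and immediate early and heat shock genes (0.396). Senescence and CDK inhibitor genes were not called by camera (0.601), but fry called the list for change in either direction (adjusted p = 0.00734). Its most abundant member, Igfbp3, which binds insulin-like growth factors, stood at 406 ± 60.3 CPM in the controls and 221 ± 96.1 CPM in the libraries labelled knockout (SD, n = 3 each), while Cdkn1c was higher. Markers of cells that the culture could carry over were too few to test: of the listed genes, 1 of microglia, 3 of endothelium, 4 of mural cells and fibroblasts, 3 of ependyma and choroid plexus and 0 of red blood cells passed the filter, as did 2 of midbrain, hindbrain and spinal cord identity and 2 of the X-inactivation and Y-linked list.

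The annotation terms deposited with the genes gave 31 called terms of 1353 by camera, 4 higher and 27 lower in the libraries labelled knockout. With an estimated correlation 0 were called (smallest adjusted p = 0.953), and with the replicate block 76 were, 8 higher and 68 lower. The lowest adjusted p belonged to the condensed chromosome kinetochore, with a mean of -0.34 over 91 genes (camera adjusted p = 2.8e-06). DNA replication initiation stood at -0.47 over 21 genes (1.2e-04) and cholesterol biosynthetic process at -0.35 over 24 genes (0.00204). The 4 higher terms were lysosome (0.11 over 208 genes, adjusted p = 0.0116), lysosomal membrane (0.12 over 170), late endosome membrane (0.11 over 93) and autolysosome (0.24 over 15).

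Across the genes tested, libraries of the same number were the most alike on average. The correlation of log2 CPM averaged 0.968 within the controls, 0.967 within the libraries labelled knockout and 0.968 between the groups, where it was 0.977 for libraries of the same number and 0.963 for the other 6 pairs. These are correlations across genes, which are not independent replicates.

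**Figure D4:**
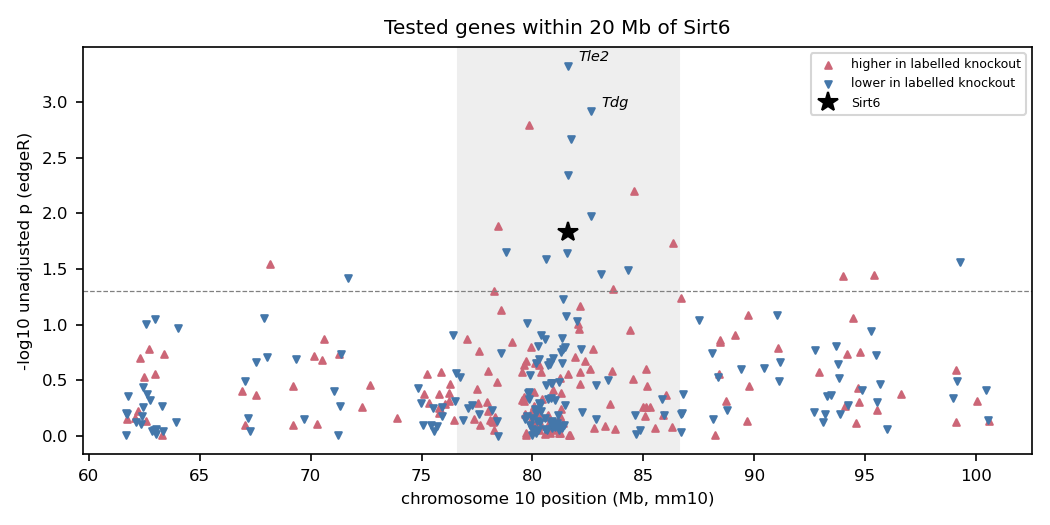
Tested genes within 20 Mb of Sirt6 on chromosome 10, by position (Mb, mm10) and by -log10 of each gene's unadjusted edgeR test value (a log scale); triangles point up for genes higher and down for genes lower in the libraries labelled knockout, the star is Sirt6, the dashed line marks the unadjusted threshold and the grey band 5 Mb to either side. Within the band 16 of 181 genes lie above the line.

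Among the 5 genes called by DESeq2, 2 lie near Sirt6 on chromosome 10: Tle2, on the plus strand from 81574561 to 81590845, and Tdg, on the plus strand from 82629828 to 82650799 (mm10). The others lie elsewhere, Mbp on chromosome 18 from 82475146 to 82585637, Parvb on chromosome 15 from 84232043 to 84315688 and Rps4l on chromosome 6 from 148354656 to 148355598. Of the 27368 genes with an adjusted p by DESeq2, 281 lie within 5 Mb of Sirt6. Tle2 lies at -0.04 Mb and Tdg at 1.02 Mb from Sirt6. Beside Tle2, Tle6 and Aes were also lower, at edgeR log2 fold changes of -1.19 and -0.49. BC025920 (0.59) and Ankrd24 (0.0095), nearer to Sirt6, were not. These neighbours were picked after their values were seen.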

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

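Alternatives with a Y-linked covariate, with control replicate 3 alone, or with a replicate block under DESeq2, limma-voom, estimated correlation or annotation terms were chosen after seeing the data; except where stated, the cause was not tested. The count of genes changed, 0 by edgeR, was 5 by DESeq2, 1 with no filter on low counts, 465 by DESeq2 with the replicate block and 0 to 2 when each library was left out. It was 0 under the other alternatives, with 1880 genes at an unadjusted p under 0.05 by edgeR and 1909 by limma-voom with the replicate block. Called gene lists, 15 by camera, were 0 with an estimated correlation, 0 with the replicate block and an estimated correlation, 0 by fry, 1 by fry for either direction, 8 with the Y-linked covariate, and 7 to 17 when each library was left out. Annotation terms, 31 by camera, were 0 with an estimated correlation and 76 with the replicate block. The mean correlation between groups, 0.968, was 0.719 over the 500 most variable genes, which leaves out the stable genes. Sirt6 kept its direction and did not reach an adjusted p under 0.05 in all 17 alternatives, at 0.51 to 0.81 when each library was left out. With the Y-linked covariate the sign turned for Rrm1 (0.075), Parp1 (0.13), Ncl (0.11) and Hmgcs1 (0.13). Against control replicate 3 alone, which leaves 1 control and ignores the replicate numbers, it turned for Rrm1 (0.096), Parp1 (0.096), Ncl (0.16), Peg3 (0.034), Hmgcs1 (0.10) and the astrocyte (-0.0096), cholesterol synthesis (0.021) and ribosome biogenesis (0.0036) lists. Cdkn1a turned to 7.2e-04 by limma-voom with the replicate block. Leaving out each library gave ranges across 0 for Cdkn1a (-0.56 to 0.51), Parp1 (-0.24 to 0.054), Eno1 (-0.064 to 0.44), Ddit4 (-0.26 to 0.45), Hmgcs1 (-0.99 to 0.090), the p53 list (-0.38 to 0.10) and the let-7 list (-0.018 to 0.93). For the called lists, 154 alternative values kept their direction and call, and 96 kept the direction but were no longer called. Estimated correlation without the block and fry reuse the means of the main fit, so the direction could not change in them. Limma on log values was not run, since counts are deposited. Depth limits genes such as Rps4l most, with 6 to 20 counts in a control library.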

Other observations

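Tests of the neighbourhood of Sirt6, of the Sirt6 counts and of the mitotic score with the replicate block were chosen only after the results were seen, and the reading of the male-share test was revised then; the tests by splits of the libraries were written down before. Across the 6 libraries the mitotic score ran from -1.23 to 1.22. The highest score lay in control replicate 2, the library with the highest Y-linked level, and the lowest in the library labelled knockout 3. The astrocyte list ran the other way in control replicate 2, with its lowest score of -1.23.

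Sirt6 reads were higher in the libraries labelled knockout. A deletion only takes reads away, so reads kept from other parts of the gene would not by themselves raise the count. The log2 fold change was 0.61 with a standard error of 0.19, and all 3 libraries lay above the controls. But no fit called the difference over all genes (edgeR adjusted p = 0.998, unadjusted p = 0.0146), and the groups were apart in 8.60% of all genes tested. Kept reads together with replicate spread are therefore not excluded. An exchange of labels between the groups cannot be told apart from correct labels: the mean CPM of the controls was 65.4% of that of the libraries labelled knockout, too high for the loss of the whole transcript, and a partial deletion leaves reads. Equal levels are not firmly excluded either. Sirt6 was named first beforehand, so its unadjusted p bears on this more than the adjusted p, and it goes against equal levels. But nothing in the labels says that the libraries came from separate animals or cultures. Increased transcription of a targeted locus that makes no functional protein is a biological explanation that was not tested.

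Within 5 Mb to either side of Sirt6, 16 of 181 tested genes had an unadjusted p under 0.05 by edgeR (8.84%), against 3.40% on the rest of chromosome 10, a ratio of 2.60. Of the runs of as many neighbouring genes elsewhere, 0.0180% held as many, and 1.26% and 0.301% did for 2 Mb and 10 Mb to either side. These runs move by 1 gene at a time and overlap, so the shares do not count separate stretches. The highest other run of 181 genes held 16 as well. Tle2 and Tdg, seen near Sirt6 beforehand, are among the 16 genes around Sirt6. With the replicate block 25 of the 181 genes had such a p (13.8%), but so did 15.3% on the rest of the chromosome, a ratio of 0.904 with 27.9% of runs holding as many, while DESeq2 with the block called 9 of 161 genes within 5 Mb (5.59%, against 3.54% elsewhere, a difference that was not tested). A chance position and a stretch of another strain's genome carried with the targeted allele, which may give such crowding, cannot be told apart, since the edgeR fits differ; without the block the share was 7.81% within 2 Mb, 11.3% from 2 to 5 Mb, 1.85% from 5 to 10 Mb, 4.35% from 10 to 20 Mb and 3.39% beyond. The requirement that both fits decide was set after these values were seen. The block raised the share to 12.3% on the other chromosomes, from 3.40% without it, so a local excess stands out less in that fit. By itself the fit without the block left few runs with as many. It cannot exclude a chance position, since the region was picked for genes that it counts. An effect of the Sirt6 locus on its neighbours was not tested.

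Mitotic genes were lower in the libraries labelled knockout, with a mean log2 fold change of -0.83. Another split of the 6 libraries reached 1.49 in size and 3 of the 10 were as large as the real one, but the larger splits part only 1 same-numbered pair; the others that part all 3 pairs gave -0.46, -0.17 and 0.19, and either set of splits is too small for a share under 0.05. A larger share of male cells in the controls is a candidate explanation that cannot be told apart from the group: the difference of the mitotic score was -0.95 ± 0.70 (SE) with the group alone, -0.95 ± 0.19 with the replicate block (95% interval -1.74 to -0.15) and -0.36 ± 0.80 with the Y-linked level as a covariate, within 1 SE of 0, which had been written beforehand as favouring it but was set aside after the value was seen, since this error leaves the opposite outcome hardly reachable. The pair differences did not follow the Y-linked level: pair 3, with 0 Y-linked CPM in both libraries, differed by -1.01, pair 2, with 234 against 0.12 CPM, by -0.60, and pair 1, with 67.5 against 0.755 CPM, by -1.23, while a fit with the replicate block and the Y-linked level gave -1.16 ± 0.22. That fit has 1 residual degree of freedom (95% interval -3.94 to 1.61). Against control replicate 3 alone, which has no Y-linked reads, the mean edgeR log2 fold change was -0.02, a measure other than the score. On the score itself control replicate 3 stood at -0.21, and the libraries labelled knockout averaged -0.47. The explanation of a larger male share in the controls therefore stays open.

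For the counts of calls, the splits are too few for a share under 0.05. EdgeR called 0 genes in the real split and at most 0 in the others, and since every split reaches a count of 0, the 10 of 10 that gave as many decide nothing. DESeq2 called 5, the highest other split gave 478, and 8 of the 10 gave as many, which points to a structure of the samples. The other splits that part all 3 same-numbered pairs gave 1, 5 and 0 calls by DESeq2 without the block. The split with 478 sets control replicates 1 and 2 and the library labelled knockout 2 against the rest. Camera called 15 lists, the highest other split gave 18, and 4 of the 10 gave as many. The other splits that part all 3 same-numbered pairs gave 18, 18 and 12 lists, so the real split does not stand out among them. Of the 4 splits that part all 3 same-numbered pairs, DESeq2 with the block called 465 genes in the real split and at most 43 in the others, which were 1, 43 and 0, so 1 of the 4 gave as many. The other 6 splits part 1 pair each and were not fitted with the block.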
